A study of Mus musculus with 30 samples.

How the data were processed

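The deposited files hold 30 tables, one per library, of counts of reads per gene symbol for 24746 symbols and 5 summary lines that name no gene. Per the labels, total RNA was extracted with Qiazol, 3′ tag libraries were made with the QuantSeq kit for Ion Torrent, and the processing used Trimmomatic 0.36, FastQC 0.11.5, STAR 2.5.3a and HTSeq with genome build mm10. The version of HTSeq, its strand setting and the annotation are not given. The values were checked to be whole numbers with different totals per library. Reads assigned to genes were 44.6 to 52.7% of all reads listed for a colon library and 46.5 to 54.1% for an ileum library, and reads that aligned to several places, which HTSeq leaves out, were 30.3 to 36.9% and 28 to 34.3%. Counts of near-identical family members, such as Defa, Hspa1a and Hspa1b, Sprr2a, Saa1 and Saa2, granzyme, Cyp4a, MHC, Gbp and Irg genes, are therefore uncertain. The 10 genes with most reads took up to 7.35% of a colon and 18.8% of an ileum library. Locations are from GENCODE vM21, in which 24160 of the symbols matched a single gene.

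Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr by group, robust quasi-likelihood fit and test), limma 3.58.1 (camera) and DESeq2 1.42.0. The 12 colon libraries (4 groups, 12855 genes tested, common biological coefficient of variation 0.28) and the 18 ileum libraries (6 groups, 13233 genes, 0.234) were fitted apart, with 1 mean per group, and all 30 together (13807 genes, 0.258) for the comparison across tissues. There were 17 comparisons: DSS within each status and COL against SPF within each treatment of the colon, the 3 pairs of statuses at each age and the ages within each status of the ileum, and 4 interactions. A gene or list was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size over the square root of the F statistic. Log CPM used a prior count of 2. A group with no count was set to a floor of 3 counts over the group, and with 1 to 3 counts a 95% binomial interval was computed.

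The comparisons, tests, lists, rule for named genes and all alternatives not said below to be added later were fixed before the data were examined. Named genes are, per comparison, the 10 largest rises and 10 largest falls with adjusted p under 0.05, mean log2 CPM of at least 3 and no overlap of the groups, leaving out predicted genes and small RNAs, then up to 4 members with the smallest p of each called list, and 15 fixed genes (Reg3b, Reg3g, Retnlb, Nos2, Duox2, Fut2, Saa1, Lcn2, Il1b, S100a8, Csf1r, Adgre1, Cx3cr1, Cd163 and Ccr2). Not every gene that this rule names is reported. Cr2 and, in ileum, Myh11 are named beyond that as list members when single libraries are described, and Sbsn was chosen after its values were seen. The 28 lists hold 499 genes, of which 489 are in the files: macrophage, monocyte and neutrophil, B and plasma cell, T and intraepithelial lymphocyte, MHC class II, cytokine, interferon-gamma, type I interferon, bacteria-induced, Paneth, goblet, tuft and mast, enteroendocrine, stem, proliferation, colonocyte, fat absorption, bile acid, sterol, xenobiotic, smooth muscle, nerve and glia, matrix and repair, adipose, immediate early, circadian, pancreas and liver, and blood genes. They were written from general knowledge of the cell types and responses, and some genes of a cell type are also expressed by other cells of the gut. A list was tested with camera at its preset correlation of 0.01 where at least 5 members passed the filter. Blood genes never reached that, and pancreas and liver genes only across tissues.

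The fit was tested on data simulated at the depth and spread of these libraries, with 200 genes changed before filtering. edgeR recovered 24.5% of 2-fold and 80.8% of 4-fold changes in colon with 4 false calls, 42.9% and 81% in ileum with 2, and 11.1% and 48.5% across tissues with 3; DESeq2 made 21, 15 and 10 false calls. Camera called a raised list and 0 of 50 random lists, which leaves correlated genes untested. Any 2 libraries of a group differed beyond counting error (chi-square per degree of freedom 5.46 to 52.2), so none resequences another.

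The alternatives were DESeq2, no filter, the scaling of DESeq2 within edgeR, only the 6 libraries of 2 groups, replicate numbers as a block, leaving out each library, and, for the lists, a correlation between genes estimated from the data. Replicate numbers come from the sample titles, and the labels give no litter, cage or day for them. Residuals of libraries with the same number were correlated at all 3 numbers only for SPF and GF ileum at 10 weeks (r = 0.25, 0.19 and 0.16, against a mean of -0.1 for different numbers), so the block was run only as an alternative. Leaving out the GF libraries numbered 1 together, single libraries for the lists, and a block with only 6 libraries were added after seeing the data. The summary lines of the files were not used as genes, and no library was left out of the values in the report.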

Results

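RNA from whole intestinal tissue of C3H/HeOuJ mice was made into 3′ tag messenger RNA libraries, in which each transcript is read near its poly(A) tail. There were 30 libraries in 10 groups of 3. Terminal ileum was taken at 6 and at 10 weeks of age from germ-free mice (GF), from mice with a specific-pathogen-free microbiota (SPF), and from germ-free mice given SPF microbiota in week 5 (COL) (18 libraries in 6 groups). Distal colon was taken at 10 weeks from SPF and COL mice, untreated or given dextran sulfate sodium (DSS), a polymer that injures the colonic epithelium, at 1.5% for 4 days followed by 2 days of water (12 libraries in 4 groups). Reads assigned to genes numbered 3830539 to 6791455 per colon library and 2233837 to 9088573 per ileum library. Levels are counts scaled to library size (CPM) as mean ± SD with n = 3 per group, and a value in parentheses after a gene is its log2 fold change ± standard error. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg correction for genes and from camera for gene lists, where a p marked "estimated" used a correlation between genes estimated from the data in place of a preset 0.01. List members counted "over the list", given where that count differs, had p adjusted over the list alone. The labels do not say that libraries of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical. Ratios against a group with 0 to 3 counts in all carry intervals or floors for counting error only, because the reads have no molecular identifiers. The series title names intestinal macrophages, while each library is of whole tissue.

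DSS in the colon of SPF mice addresses what this injury does to gene expression under an SPF microbiota. Clca4b (chromosome 3, 144910921 to 144932529 in mm10 with GENCODE vM21, protein-coding like every gene placed below), a regulator of epithelial chloride channels, rose from 2.21 ± 2.11 to 708 ± 151 CPM (log2 fold change 8.23 ± 0.69, adjusted p = 2.2e-05). Ido1 (chromosome 8, 24584136 to 24597009), which encodes a tryptophan-degrading enzyme induced by interferon, rose 669-fold (95% interval 185 to 5530). Psmb8 (chromosome 17, 34197721 to 34201454), a subunit of the immunoproteasome, rose from 56.1 ± 12.5 to 523 ± 45.5 CPM (3.22 ± 0.28, adjusted p = 6.5e-06). Clca1 (chromosome 3, 145003817 to 145032776), a secreted goblet cell protein, fell from 2130 ± 289 to 237 ± 169 CPM (-3.17 ± 0.58, adjusted p = 0.0024). Cyp2c55 (chromosome 19, 39007019 to 39042693), a colonic cytochrome P450, fell from 301 ± 72.8 to 6.01 ± 2.71 CPM (-5.62 ± 0.54, adjusted p = 4.8e-05). For every gene said to rise or fall, all 3 libraries of one group lay above all 3 of the other unless stated, partly by selection. Between 2 groups 10.2 to 34.5% of all genes did so (10% by chance). In all, 1570 of 12855 tested genes rose and 1527 fell. The total of 3097 became 2021 without SPF DSS replicate 2 and 1915 without SPF DSS replicate 3.

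Interferon-gamma response genes rose in 20 of 21 tested, 21 over the list (median 3.37, adjusted p = 3.1e-22, 0.13 estimated). Among them Psmb9 (3.17 ± 0.37), Tap1 (3.21 ± 0.40), which loads peptides onto MHC class I, and the T-cell attractant Cxcl9 (6.83 ± 0.79) rose. Type I interferon genes rose in 6 of 22 tested, 8 over the list (median 1.15, adjusted p = 5.2e-05, 0.32 estimated). Ifi44 (3.60 ± 0.63) and Zbp1 (2.38 ± 0.41) rose among them. MHC class II genes rose in 5 and fell in 1 of 10 tested, 6 up and 1 down over the list (median 1.26, adjusted p = 0.0099, 0.31 estimated). H2-DMb1 (3.02 ± 0.36) and Cd74 (2.10 ± 0.38) rose and the protease gene Ctse (-2.17 ± 0.44) fell. Cell-cycle genes rose in 19 of 22 tested, 20 over the list (median 1.68, adjusted p = 7.4e-17, 0.13 estimated). Plk1 (2.16 ± 0.28) and Top2a (1.82 ± 0.26) rose among them. Sterol synthesis genes rose in 12 of 20 tested, 13 over the list (median 1.22, adjusted p = 5.4e-10, 0.13 estimated). Fdft1 (2.16 ± 0.25) and Fdps (2.10 ± 0.25), enzymes of the mevalonate route, rose among them. The bile acid transporter subunit Slc51b (3.08 ± 0.37) rose in a list called upward (median 0.88, 3 up and 1 down of 5 over the list, adjusted p = 0.039, 0.15 estimated).

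Genes that bacteria induce in epithelium rose in 7 and fell in 1 of 14 tested (median 2.14, adjusted p = 0.0031, 0.13 estimated) after DSS in SPF colon. The inducible nitric oxide synthase gene Nos2 (4.21 ± 0.73, adjusted p = 0.0024), Fut2 (2.9 ± 0.41), a fucosyltransferase of the mucosal surface, and Duoxa2 (2.67 ± 0.37), which matures an epithelial oxidase, rose. The antimicrobial lectin genes Reg3b (3.20 ± 1.75, adjusted p = 0.22) and Reg3g (2.81 ± 1.56, adjusted p = 0.22) did not pass. Cytokine genes rose in 6 of 11 tested, 7 over the list (median 1.71, adjusted p = 0.0019, 0.18 estimated). Tnf (3.15 ± 0.50) and the neutrophil attractant Cxcl1 (4.39 ± 0.88) rose, and Cxcl5 rose 896-fold (95% interval 160 to 35400). Monocyte and neutrophil genes rose in 6 of 9 tested (median 1.93, adjusted p = 0.012, 0.18 estimated). Plac8 (1.23 ± 0.26) and the monocyte chemokine receptor Ccr2 (1.75 ± 0.44) rose among them.

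Neutrophil and cytokine genes were uneven between the DSS-treated SPF libraries. In replicates 1, 2 and 3, S100a8 was 4.38, 47.6 and 560 CPM, Il1b 6.2, 11.8 and 193 CPM and Cxcl5 4.56, 30.3 and 189 CPM. The Cxcl5 ratio was 231 without replicate 3 and 1390 without replicate 1, and Cxcl1 rose by 2.77 log2 without replicate 3. S100a8 had adjusted p = 0.015, and 0.061, 0.053 and 0.055 without untreated SPF replicates 1, 2 and 3 (range over alternatives 9.1e-07 to 0.061). Il1b had adjusted p = 0.012, and 0.054 and 0.051 without untreated SPF replicates 1 and 3 (range 4.4e-06 to 0.071). Macrophage genes rose in 3 and fell in 1 of 20 tested (median 0.10, adjusted p = 0.65). The colony-stimulating factor receptor gene Csf1r (chromosome 18, 61100598 to 61132149) was 15.2 ± 9.15 CPM after DSS and 20.7 ± 7.75 CPM without (-0.45 ± 0.39, adjusted p = 0.42), and Adgre1 (-0.38 ± 0.46, adjusted p = 0.57), which encodes the macrophage antigen F4/80, did not pass.

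After DSS in SPF mice goblet and mucus genes fell in 11 of 15 tested (median -1.52, adjusted p = 1.1e-05, 0.18 estimated). The mucus protein Fcgbp (-1.77 ± 0.38) and the secretory-lineage factor Atoh1 (-1.27 ± 0.28) fell among them. Colonocyte genes fell in 7 of 16 tested, 10 over the list (median -1.17, adjusted p = 1.1e-05, 0.13 estimated). The anion exchanger Slc26a3 (-1.83 ± 0.27) and the water channel Aqp8 (-1.68 ± 0.34) fell among them. Xenobiotic genes fell in 6 of 14 tested (median -0.93, adjusted p = 1.6e-05, 0.13 estimated). Cyp2d26 (-4.39 ± 0.45) and the drug efflux pump Abcb1a (-2.71 ± 0.41) fell among them. Enteroendocrine genes rose in 1 and fell in 6 of 13 tested, 1 up and 8 down over the list (median -1.05, adjusted p = 0.014, 0.18 estimated), with the hormones Pyy (-1.20 ± 0.26) and Insl5 (-1.37 ± 0.29) lower. Smooth muscle genes fell in 13 of 16 tested, 15 over the list (median -1.61, adjusted p = 1.1e-08, 0.18 estimated). The myosin gene Myh11 (-2.19 ± 0.48) fell among them. Enteric nerve and glia genes fell in 5 of 15 tested, 6 over the list (median -0.92, adjusted p = 0.0026, 0.15 estimated). Stmn2 (-1.64 ± 0.34) fell among them. Matrix and repair genes rose in 2 and fell in 7 of 17 tested, 2 up and 8 down over the list (median -0.51, adjusted p = 0.027, 0.13 estimated). Col3a1 (-1.71 ± 0.23) fell while the matrix protease Mmp3 (3.17 ± 0.69) rose.

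Circadian genes rose in 2 and fell in 6 of 14 tested, 3 up and 7 down over the list (median -0.85, adjusted p = 0.097) without a call of the list, although the output regulator Dbp (-3.87 ± 0.65) fell in SPF colon. Paneth, tuft and mast, stem, B and plasma, and T cell, fat absorption, immediate early and adipose genes (adjusted p = 0.13 to 0.97) were not called as lists either.

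**Figure D1:**
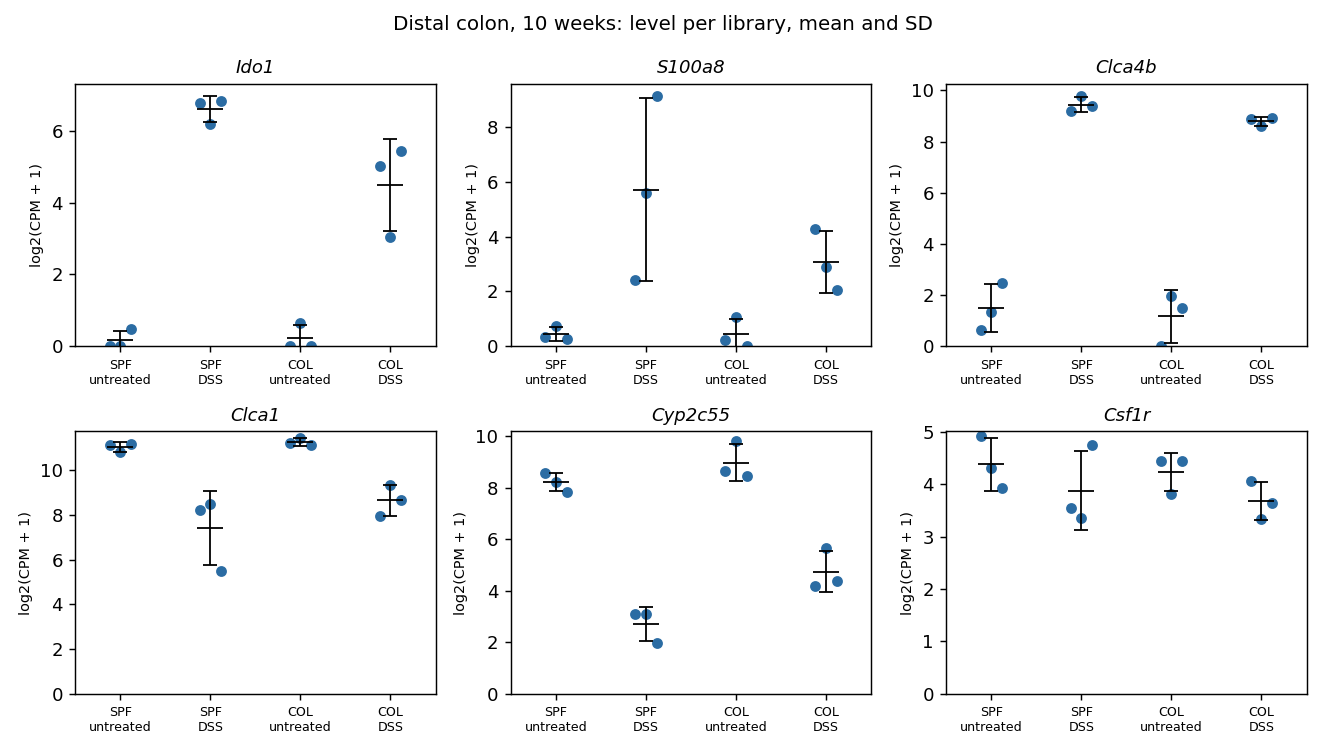
Expression of Ido1, S100a8, Clca4b, Clca1, Cyp2c55 and Csf1r in the 4 colon groups, as log2(CPM + 1) per library on the y axis; points are libraries, bars the mean and SD of 3. Clca4b stood at 708 ± 151 CPM in DSS-treated SPF colon.

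DSS in the colon of COL mice asks the same of animals that met a microbiota only in week 5. Clca4b (447 ± 52.6 against 1.59 ± 1.48 CPM, log2 fold change 8.16 ± 0.69, adjusted p = 3.3e-05), the lysolipid carrier gene Mfsd2a (6.15 ± 0.56), the cell-surface antigen gene Ly6a (4.70 ± 0.44) and Il18bp (4.69 ± 0.65), whose product binds interleukin-18, rose, and Ido1 rose 157-fold (95% interval 53.4 to 764). Cyp2c55 (-4.24 ± 0.49) and the manganese exporter Slc30a10 (-5.48 ± 0.65) fell. In all 532 genes rose and 386 fell. The total of 918 became 602, 573 and 511 without COL DSS replicates 1, 2 and 3, and 376, 436 and 476 without untreated COL replicates 1, 2 and 3. Across genes, which are not independent replicates, the fold changes in SPF and COL colon had Pearson r = 0.74, with no library shared. Of the called genes 415 rose in both (65 by chance) and 290 fell in both (45.9 by chance).

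Interferon-gamma genes in COL colon rose in 18 of 21 tested, 20 over the list (median 2.93, adjusted p = 1.9e-27, 0.05 estimated). Proliferation genes rose in 18 of 22 tested, 20 over the list (median 1.69, adjusted p = 7.1e-28, 0.047 estimated). Ccnb2 (2.33 ± 0.31) rose among them. Sterol synthesis genes rose in 13 of 20 tested, 15 over the list (median 1.36, adjusted p = 2.5e-21, 0.047 estimated). Bacteria-induced genes rose in 5 of 14 tested (median 1.28, adjusted p = 8.2e-05, 0.047 estimated). Fut2 (3.18 ± 0.41) and the goblet cell protein Retnlb (2.96 ± 0.57) rose among them. Clock genes fell in 5 of 14 tested, 7 over the list (median -1.19, adjusted p = 0.0012, 0.047 estimated). Per2 (-1.69 ± 0.31) fell among them. The cytokine gene Tnf (3.77 ± 0.57), bile acid gene Slc51b (2.48 ± 0.36) and monocyte-list gene Plac8 (1.29 ± 0.26) rose. Their lists were called upward, as were MHC class II and type I interferon genes (adjusted p = 0.0055, 0.042, 0.013, 0.0012 and 3.6e-05, and 0.2, 0.17, 0.2, 0.2 and 0.3 estimated).

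Smooth muscle genes in COL colon fell in 3 of 16 tested, 9 over the list (median -1.03, adjusted p = 4.9e-07, 0.2 estimated). Fat absorption genes rose in 1 and fell in 4 of 14 tested, 1 up and 5 down over the list (median -0.31, adjusted p = 0.0041, 0.071 estimated). The sterol transporters Abcg5 (-3.17 ± 0.50) and Abcg8 (-3.04 ± 0.47) fell. The heat-shock genes Hspa1a (-2.82 ± 0.47) and Hspa1b (-2.09 ± 0.42), near-identical copies that share reads, fell within the immediate early list, called downward (median -0.48, 4 down of 16 over the list, adjusted p = 0.0097, 0.17 estimated). This fall starts from a high level in untreated COL colon, 113 ± 70 and 218 ± 115 CPM, against 21.7 ± 7.44 and 51.7 ± 16.3 CPM in untreated SPF and 28.5 ± 13.1 and 52.3 ± 23.7 CPM in DSS-treated SPF colon. Colonocyte, xenobiotic, enteroendocrine, nerve and glia, and B and plasma cell genes, among them the neuroendocrine gene Pcsk1n (-2.51 ± 0.52), were called downward with medians -0.78, -0.43, -0.44, -0.79 and -1.01 (adjusted p = 8.2e-05, 0.0035, 0.012, 0.0012 and 0.0052, and 0.17, 0.2, 0.18, 0.17 and 0.36 estimated). Goblet genes (adjusted p = 0.065) and macrophage genes (0.92) were not called.

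Whether DSS acted differently in COL and SPF colon was tested as an interaction, the COL effect minus the SPF effect. By edgeR 0 genes passed, with 1122 at unadjusted p under 0.05 (643 by chance) and 17 by DESeq2. Leaving out SPF DSS replicate 1 or untreated SPF replicate 2 gave 1 gene each. Goblet and mucus genes were less reduced in COL (median 0.82, adjusted p = 4.9e-05, 0.57 estimated), among them the main intestinal mucin Muc2 (1.60 ± 0.69, adjusted p = 0.56). Xenobiotic, smooth muscle, matrix, immediate early, fat absorption and interferon-gamma genes were also called, with medians 0.60, 0.46, 0.30, -0.28, -0.21 and -0.44 (adjusted p = 0.0027, 0.034, 0.043, 0.0027, 0.04 and 0.039, and 0.53, 0.82, 0.34, 0.34, 0.35 and 0.82 estimated). Without SPF DSS replicate 3 smooth muscle had adjusted p = 0.34, and type I interferon and B and plasma cell genes, at 0.39 and 0.35 with all libraries, had 0.0074 and 0.0035.

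Untreated COL against untreated SPF colon addresses whether late colonization leaves a mark at 10 weeks. By edgeR 0 of 12855 genes passed, with 988 at unadjusted p under 0.05 (643 by chance) and 28 by DESeq2. Leaving out untreated SPF replicate 2 gave 1 gene and replicate 3 gave 94. Type I interferon genes lay higher in COL (median 0.40, adjusted p = 0.021, 0.93 estimated), among them the antiviral genes Mx2 (1.58 ± 0.66, adjusted p = 0.61) and Isg15 (0.95 ± 0.47, adjusted p = 0.67). Hspa1a (2.38 ± 0.46, adjusted p = 0.26) and Hspa1b (2.08 ± 0.42, adjusted p = 0.27) were higher in COL without overlap and did not pass. The macrophage gene Csf1r (-0.17 ± 0.38, adjusted p = 0.94) and the lectin gene Reg3g (1.84 ± 1.55, adjusted p = 0.82) did not pass.

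After DSS, COL against SPF colon compares the injured tissues directly. The single called gene was Efna2 (chromosome 10, 80179482 to 80190010), an ephrin that mediates cell contacts, at 13.3 ± 3.34 against 1.36 ± 0.936 CPM (log2 fold change 3.32 ± 0.48, adjusted p = 0.032), with 1030 genes at unadjusted p under 0.05 and 5 called by DESeq2. Its adjusted p was 0.45, 0.19 and 0.15 without SPF DSS replicate 2, COL DSS replicate 1 and COL DSS replicate 2 (range over alternatives 6.7e-07 to 0.45). The count became 29 without SPF DSS replicate 1 and 0 without any one of those 3 libraries. Monocyte and neutrophil genes lay lower in COL (median -2.26, 3 down of 9 over the list, adjusted p = 0.035, 0.33 estimated), among them S100a8 (-4.41 ± 1.46, adjusted p = 0.54). Cytokine genes lay lower too (median -1.16, 5 down of 11 over the list, adjusted p = 4.8e-05, 0.3 estimated), among them Il1b (-3.32 ± 1.14, adjusted p = 0.55), as did immediate early and proliferation genes with medians -0.45 and -0.18 (adjusted p = 0.00092 and 0.036, and 0.3 and 0.86 estimated). Goblet genes lay higher (median 0.77, 1 up of 15 over the list, adjusted p = 1.4e-08, 0.3 estimated), as did xenobiotic, smooth muscle and colonocyte genes with medians 0.61, 0.42 and 0.35 (adjusted p = 6.1e-05, 0.004 and 0.021, and 0.3, 0.63 and 0.41 estimated). SPF DSS replicate 3 gave most of the S100a8 and Il1b gap. Without it adjusted p was 0.24 for monocyte and neutrophil, 0.65 for proliferation, 0.68 for colonocyte and 0.26 for smooth muscle genes. Interferon-gamma and matrix genes, at 0.35 and 0.18 with all libraries, reached 0.027 and 0.043.

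SPF against germ-free ileum at 6 weeks addresses what a microbiota does to the young small intestine. Reg3g (chromosome 6, 78466269 to 78468872), a secreted lectin that kills Gram-positive bacteria, rose from 1720 ± 650 to 48800 ± 18300 CPM (log2 fold change 4.83 ± 0.57, adjusted p = 9.1e-05). Nos2 (chromosome 11, 78920787 to 78960254) rose from 4.76 ± 2.86 to 352 ± 165 CPM (6.23 ± 0.61, adjusted p = 3.2e-05), and Jchain (chromosome 5, 88519809 to 88527891), which joins secreted IgA, from 54.2 ± 31.3 to 647 ± 29.9 CPM (3.59 ± 0.38, adjusted p = 2e-05). Fabp1 (chromosome 6, 71199827 to 71205023), a fatty acid carrier of enterocytes, fell from 235 ± 42.3 to 16.4 ± 0.984 CPM (-3.84 ± 0.47, adjusted p = 0.00013). Fut2 (chromosome 7, 45648591 to 45666394) had no read in any of the 6 germ-free ileum libraries and was at least 779-fold higher in SPF (floor of 3 counts over the group, adjusted p = 0.0094, or 0.09 when only the 6 libraries were fitted, range 2e-12 to 0.09). The acute-phase gene Saa1 (10.17 ± 1.11) rose, and the fatty acid hydroxylase gene Cyp4a10 was 759-fold (95% interval 136 to 30000) lower. In all 578 of 13233 genes rose and 440 fell. The total of 1018 became 529 without GF replicate 2, 513 without SPF replicate 1 and 539 without SPF replicate 2.

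Bacteria-induced epithelial genes in 6-week SPF ileum rose in 13 of 18 tested, 15 over the list (median 2.57, adjusted p = 2.6e-30, 0.0095 estimated). Pigr (2.47 ± 0.20), the receptor that carries IgA across epithelium, and Reg3b (3.41 ± 0.43) rose among them. Interferon-gamma genes rose in 15 of 21 tested, 21 over the list (median 2.23, adjusted p = 2.3e-50, 4e-04 estimated). The GTPases Irgm2 (3.18 ± 0.21) and Gbp7 (2.35 ± 0.22) rose among them. MHC class II genes rose in 4 of 11 tested, 5 over the list (median 1.53, adjusted p = 8.3e-10, 0.058 estimated). H2-DMb1 (4.19 ± 0.27) and Cd74 (2.98 ± 0.34) rose among them. Type I interferon genes rose in 7 of 22 tested, 8 over the list (median 0.76, adjusted p = 1.4e-05, 0.15 estimated). The nucleic acid sensor Zbp1 (4.30 ± 0.54) rose among them. Paneth cell genes rose in 6 and fell in 1 of 15 tested, 9 up and 1 down over the list (median 0.93, adjusted p = 4.5e-09, 0.14 estimated). The pentraxin gene Mptx2 rose 313-fold (95% interval 107 to 1520) and the phospholipase Pla2g2a (1.67 ± 0.22) rose. T cell and intraepithelial lymphocyte genes rose in 9 of 19 tested, 12 over the list (median 2.52, adjusted p = 3.7e-11, 0.062 estimated). Gzma (5.67 ± 0.78) of cytotoxic granules rose among them. B and plasma cell genes rose in 4 of 16 tested (median -2.26, or -2.05 with members at their floor, adjusted p = 0.0011, 0.38 estimated), a list that camera called upward through plasma cell genes such as Derl3 (3.69 ± 0.35) and Tnfrsf17 (3.69 ± 0.53), although its median and its mean of -1.33 were negative.

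Macrophage genes in 6-week SPF ileum rose in 4 of 19 tested, 5 over the list (median 0.40, adjusted p = 0.0018, 0.066 estimated). The lysosomal protease Lgmn (1.92 ± 0.35) rose among them. Csf1r (0.24 ± 0.29, adjusted p = 0.71) and Cx3cr1 (0.44 ± 0.31, adjusted p = 0.45), a receptor of resident gut macrophages, did not pass. Monocyte and neutrophil genes rose in 2 of 6 tested (median 0.37, adjusted p = 0.0011, 0.03 estimated). Ly6c2 (3.76 ± 0.30) rose. Cytokine genes rose in 2 of 8 tested, 5 over the list (median 2.36, adjusted p = 3e-04, 0.052 estimated), with Ccl4 up 42.5-fold (95% interval 11.5 to 356). Fat absorption genes fell in 5 of 19 tested, 2 up and 6 down over the list (median -0.24, adjusted p = 0.0017, 0.23 estimated). Fabp2 (-1.44 ± 0.23) and the fasting-induced gene Pdk4 (-2.75 ± 0.31) fell. Xenobiotic genes rose in 1 and fell in 4 of 16 tested, 1 up and 5 down over the list (median -0.58, adjusted p = 0.006, 0.19 estimated). Cyp2d26 (-2.70 ± 0.29) fell among them. Colonocyte genes fell in 4 of 11 tested, 2 up and 5 down over the list (median -0.19, adjusted p = 0.0047, 0.15 estimated). The steroid enzyme Hsd11b2 (-1.19 ± 0.19) fell among them. Proliferation, bile acid and immediate early genes were called upward with medians 0.45, 0.44 and 0.37 (adjusted p = 0.0016, 0.048 and 0.019, and 0.27, 0.28 and 0.14 estimated); without replicate 1 of both germ-free groups, whose lymphocyte genes were high, bile acid genes had 0.098 and immediate early genes 0.078. Adipose and mesentery genes were called downward (median -4.02, 8 down of 11 over the list, adjusted p = 0.0018, 0.38 estimated).

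COL against germ-free ileum at 6 weeks shows the tissue soon after colonization in week 5. Reg3g (68700 ± 19100 against 1720 ± 650 CPM, log2 fold change 5.32 ± 0.58, adjusted p = 0.00011), Saa1 (9.92 ± 1.10), Nos2 (5.55 ± 0.60) and Dmbt1 (4.57 ± 0.40), a mucosal receptor that binds bacteria, rose, and Mptx2 rose 847-fold (95% interval 289 to 4110). Fabp1 (-2.94 ± 0.45) and the nucleoside transporter Slc28a1 (-3.57 ± 0.53) fell. Fut2 was at least 437-fold higher (289 without COL replicate 2; adjusted p = 0.021); its adjusted p was 0.051, 0.072 and 0.066 without GF replicates 1, 2 and 3 and 0.058 and 0.055 without COL replicates 2 and 3 (range 1.2e-10 to 0.087). In all 368 genes rose and 246 fell. The total of 614 became 311 and 381 without GF replicates 2 and 3 and 331 and 324 without COL replicates 2 and 3. The COL and SPF comparisons share the GF libraries. Their fold changes had r = 0.73 across genes, against a mean of 0.5 in 20 simulations where neither group changed. In both, 276 genes rose and 178 fell, and what the shared libraries add was not tested.

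Bacteria-induced genes in 6-week COL ileum rose in 14 of 18 tested (median 2.74, adjusted p = 1.3e-36, 0.0033 estimated). Pigr (2.03 ± 0.20) and Retnlb (3.12 ± 0.56) rose among them. Interferon-gamma genes rose in 14 of 21 tested, 15 over the list (median 1.53, adjusted p = 6.1e-32, 0.0033 estimated). Irgm2 (2.67 ± 0.21) rose. The type I interferon genes rose in 9 of 22 tested, 17 over the list (median 1.22, adjusted p = 2.7e-17, 0.022 estimated). Ifit3 (2.60 ± 0.42) and Isg15 (2.13 ± 0.39) rose among them. Paneth cell genes rose in 7 and fell in 1 of 15 tested, 12 up and 1 down over the list (median 1.26, adjusted p = 1.4e-19, 0.04 estimated). Defa24 (1.76 ± 0.28), a defensin of a family that shares reads, rose among them. MHC class II genes rose in 1 of 11 tested (median 0.38, adjusted p = 0.025, 0.48 estimated). H2-DMb1 (2.07 ± 0.25) rose. Macrophage genes rose in 2 of 19 tested, 3 over the list (median 0.33, adjusted p = 0.029, 0.19 estimated). Xenobiotic genes fell in 3 of 16 tested, 6 over the list (median -0.51, adjusted p = 1.7e-06, 0.046 estimated). Proliferation, immediate early and enteroendocrine genes, with Cdk1 (0.98 ± 0.22), Atf3 (1.56 ± 0.25) and the hormone Cck (1.48 ± 0.26), were called upward (adjusted p = 2e-08, 0.0056 and 0.028, and 0.081, 0.081 and 0.43 estimated), and colonocyte and adipose genes, with Guca2a (-1.11 ± 0.19) of the former, downward (adjusted p = 0.028 and 0.025, and 0.23 and 0.56 estimated). T cell (adjusted p = 0.45), B and plasma cell (0.62) and sterol genes (0.085) were not called, although T cell genes had 3.5e-05 and sterol genes 0.027 without replicate 1 of both germ-free groups.

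Direct comparison of COL with SPF ileum at 6 weeks asks how newly and lifelong colonized tissue differ. Jchain was 46.3 ± 16 against 647 ± 29.9 CPM (log2 fold change -3.81 ± 0.39, adjusted p = 0.00014), and the plasma cell genes Derl3 (-2.48 ± 0.32) and Tnfrsf17 (-4.08 ± 0.56), the monocyte gene Ly6c2 (-3.63 ± 0.30) and H2-DMb1 (-2.12 ± 0.24) were lower in COL. Cd74 (-2.22 ± 0.33, adjusted p = 0.0063) was lower too, with adjusted p = 0.083 and 0.071 without COL replicates 2 and 3 (range 1.6e-10 to 0.083). The transcription factor gene Tfcp2l1 (1.58 ± 0.23, adjusted p = 0.00072) was higher. In all 3 genes were higher and 10 lower in COL, and the total of 13 became 8 without COL replicate 3. T cell (median -2.71, 12 down of 19 over the list, adjusted p = 3.6e-21, 0.037 estimated), interferon-gamma (median -0.77, 8 down of 21 over the list, adjusted p = 2.4e-13, 0.044 estimated) and monocyte and neutrophil genes (median -0.66, 2 down of 6 over the list, adjusted p = 1.1e-06, 0.0093 estimated) lay lower in COL, as did MHC class II (median -1.47, 7 down of 11 over the list, adjusted p = 8.6e-12, 0.051 estimated) and B and plasma cell genes (median -1.47, or -0.54 with members at their floor, 4 down of 16 over the list, adjusted p = 4e-10, 0.2 estimated). Cytokine and xenobiotic genes lay lower with medians -0.51 and -0.36 (adjusted p = 0.0039 and 0.02, and 0.12 and 0.34 estimated). Type I interferon genes lay higher (median 0.48, 4 up of 22 over the list, adjusted p = 1.1e-06, 0.18 estimated), as did Paneth cell, fat absorption, stem and proliferation genes with medians 0.54, 0.10, 0.19 and 0.19 (adjusted p = 0.00016, 0.0039, 0.018 and 0.0075, and 0.37, 0.34, 0.22 and 0.38 estimated). The lectin gene Reg3g (0.49 ± 0.48, adjusted p = 0.85) did not pass.

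**Figure D2:**
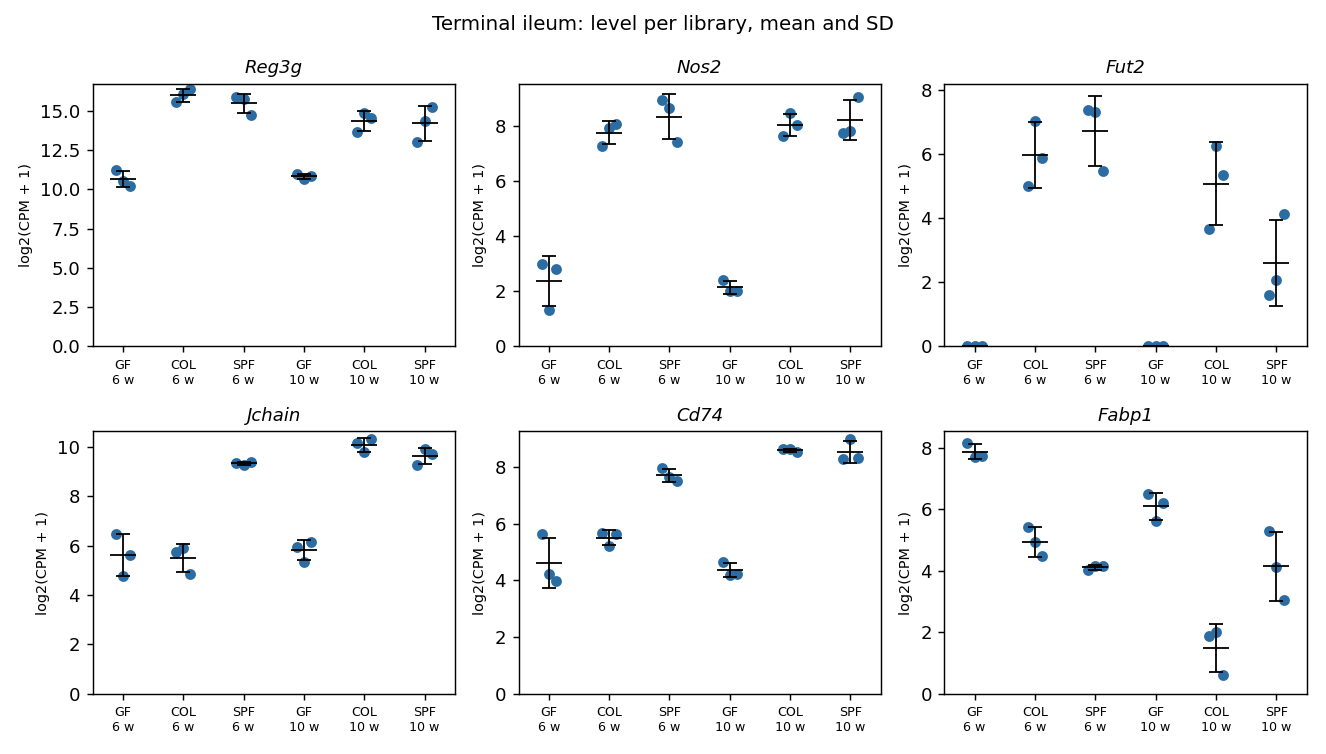
Expression of Reg3g, Nos2, Fut2, Jchain, Cd74 and Fabp1 in the 6 ileum groups, as log2(CPM + 1) per library on the y axis; points are libraries, bars the mean and SD of 3. Fut2 had no read in the GF libraries, and Jchain stood at 647 ± 29.9 CPM in 6-week SPF ileum.

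SPF against germ-free ileum at 10 weeks addresses the same question in older mice. The cytotoxic granule genes Gzma (8.32 ± 0.91, adjusted p = 0.00013) and Nkg7 (5.88 ± 0.69) rose, and Gzmb rose 431-fold (95% interval 76.9 to 17100). Ceacam10 (chromosome 7, 24777206 to 24784657), a secreted member of the CEA family, rose (6.73 ± 0.64, adjusted p = 9.4e-06), as did the chemokine Ccl5 (6.59 ± 1.07), Nos2 (6.54 ± 0.64), Saa1 (7.23 ± 1.03), Reg3g (3.65 ± 0.54) and Reg3b (2.49 ± 0.41). Fut2, with 65 reads in the group (7.17 ± 7.95 CPM), was at least 25.1-fold higher (39.8 and 14 without SPF replicates 1 and 3) and did not pass (adjusted p = 0.23, range 4.2e-05 to 0.41). Slc28a1 (-3.16 ± 0.53) and Efna2 (-2.34 ± 0.39) fell, and Cyp4a10 was 85.4-fold (95% interval 23.3 to 710) lower. In all 559 genes rose and 262 fell. The total of 821 became 515, 462 and 437 without GF replicates 1, 2 and 3. SPF fold changes at 6 and 10 weeks, from separate libraries, had r = 0.47 across genes, with 228 genes up at both ages (24.4 by chance), 149 down at both (8.71 by chance) and 3 in opposite directions.

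T cell and intraepithelial lymphocyte genes in 10-week SPF ileum rose in 17 of 19 tested (median 4.56, adjusted p = 1.8e-30, 0.0065 estimated). The integrin Itgae (3.36 ± 0.46), which holds these cells in epithelium, rose and Cd8a rose 212-fold (95% interval 37.6 to 8420). The MHC class II genes rose in 8 of 11 tested, 10 over the list (median 3.86, adjusted p = 2.8e-25, 0.0051 estimated). Cd74 (4.27 ± 0.37) and H2-Aa (4.64 ± 0.65) rose among them. Interferon-gamma genes rose in 18 of 21 tested, 21 over the list (median 2.83, adjusted p = 1.6e-73, 8e-05 estimated). Irgm2 (3.85 ± 0.22) rose. The type I interferon genes rose in 8 of 22 tested, 10 over the list (median 0.70, adjusted p = 1.8e-08, 0.07 estimated). B and plasma cell genes rose in 4 of 16 tested, 5 over the list (median 3.51, adjusted p = 4.6e-09, 0.14 estimated). Jchain (3.83 ± 0.38) rose. The median rests on SPF replicate 1, without which it was -0.09 (adjusted p = 3.3e-05): the follicular B cell gene Cr2 was 125, 0.599 and 0.48 CPM in replicates 1, 2 and 3, and the mean of 6 follicle genes, relative to its mean over ileum, 5.27, -0.93 and -1.39 log2 in SPF and 2.04, -1.77 and -1.23 in GF. Bacteria-induced genes rose in 8 and fell in 1 of 18 tested, 11 up and 1 down over the list (median 2.02, or 1.80 with members at their floor, adjusted p = 5.3e-16, 0.029 estimated). Pigr (2.15 ± 0.20) rose. Paneth cell genes rose in 7 of 15 tested, 9 up and 1 down over the list (median 1.13, adjusted p = 3.9e-07, 0.16 estimated).

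Macrophage genes in 10-week SPF ileum rose in 6 of 19 tested, 10 over the list (median 0.79, adjusted p = 3.9e-07, 0.0067 estimated). The complement genes C1qa (chromosome 4, 136895917 to 136898803; 1.07 ± 0.22) and C1qc (1.64 ± 0.28), made by tissue macrophages, rose. Cx3cr1 (1.14 ± 0.32, adjusted p = 0.032) passed, with adjusted p = 0.14 and 0.071 without SPF replicates 1 and 2 and 0.1 and 0.2 without GF replicates 2 and 3 (range 0.01 to 0.2). Csf1r (0.67 ± 0.29, adjusted p = 0.21) and Adgre1 (1.58 ± 0.62, adjusted p = 0.14) did not pass. Monocyte and neutrophil genes rose in 2 of 6 tested (median 0.85, adjusted p = 0.00091, 0.031 estimated). Ly6c2 (3.21 ± 0.28) rose. Cytokine genes rose in 2 of 8 tested, 3 over the list (median 1.17, adjusted p = 0.0012, 0.07 estimated). Tnf (4.56 ± 0.91) rose. The sterol gene Cyp51 (-0.85 ± 0.19) and the colonocyte gene Hsd11b2 (-1.52 ± 0.19) fell within lists called downward, with medians -0.45 and -0.38 (adjusted p = 6.1e-06 and 0.00027, and 0.12 and 0.07 estimated). Proliferation genes lay higher (median 0.35, 1 up of 22 over the list, adjusted p = 0.0056, 0.33 estimated).

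Smooth muscle genes lay lower in 10-week SPF than GF ileum (median -1.09, adjusted p = 2.4e-09, 0.16 estimated), and the myosin gene Myh11 was 14.4 CPM in SPF replicate 3, the library of lowest depth, against 199 and 293 CPM in the other two. Without that library the smooth muscle median was -0.63 (adjusted p = 1.2e-08), proliferation genes had adjusted p = 0.064, and fat absorption and stem cell genes, at 0.081 and 0.071 with all libraries, had 0.01 and 0.03. Without SPF replicate 1, enteroendocrine and tuft and mast cell genes, at 0.11 and 0.067 with all libraries, had 0.0062 and 0.0099. Without replicate 1 of both germ-free groups adjusted p was 0.054 for proliferation and 0.014 for fat absorption genes.

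COL against germ-free ileum at 10 weeks shows the tissue later in colonization. Cd74 (chromosome 18, 60803848 to 60812652), the invariant chain of MHC class II, rose from 19.7 ± 3.71 to 385 ± 14.7 CPM (log2 fold change 4.29 ± 0.37, adjusted p = 8.1e-07). Ceacam10 (6.88 ± 0.64), Saa1 (9.13 ± 1.08), Nos2 (6.29 ± 0.63), Reg3g (3.62 ± 0.53) and Gzma (6.04 ± 0.91) rose. Fabp1 (-5.06 ± 0.57) fell, to 2.64, 3.03 and 0.513 CPM in the 3 COL libraries, as did the lipase-like Aadac (-2.92 ± 0.31). Fut2 was at least 238-fold higher (144 without COL replicate 2; adjusted p = 0.022), with adjusted p = 0.065 and 0.05 without COL replicates 2 and 3 and 0.054, 0.068 and 0.063 without GF replicates 1, 2 and 3 (range 3.2e-09 to 0.1). In all 675 genes rose and 534 fell. The total of 1209 became 713 without COL replicate 2 and 802 and 760 without GF replicates 2 and 3. COL fold changes at 6 and 10 weeks had r = 0.3 across genes, with 188 genes up (18.8 by chance) and 161 down (9.93 by chance) at both ages. Against SPF, with shared GF libraries, r was 0.85 (0.49 simulated without change), and 420 genes rose and 185 fell in both.

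Macrophage genes in 10-week COL ileum rose in 9 of 19 tested, 14 over the list (median 1.00, adjusted p = 2.5e-10, 0.003 estimated). C1qa (1.62 ± 0.22), C1qc (1.79 ± 0.28) and the actin-binding gene Aif1 (1.67 ± 0.36) rose among them. Cx3cr1 (1.17 ± 0.32, adjusted p = 0.019) passed, with adjusted p = 0.053 and 0.051 without COL replicates 2 and 3 and 0.065 and 0.14 without GF replicates 2 and 3 (range 0.005 to 0.14). Adgre1 (2.26 ± 0.59, adjusted p = 0.014) passed, with adjusted p = 0.077 without COL replicate 2 and 0.078 without GF replicate 1 (range 0.0035 to 0.084), and Csf1r (0.85 ± 0.29, adjusted p = 0.065) did not pass. Monocyte and neutrophil genes rose in 2 and fell in 1 of 6 tested, 3 up and 1 down over the list (median 0.74, adjusted p = 0.0028, 0.041 estimated). Ly6c2 (3.44 ± 0.28) rose. Cytokine genes rose in 2 of 8 tested, 5 over the list (median 1.51, adjusted p = 0.00036, 0.041 estimated). Tnf (4.23 ± 0.91) rose.

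Interferon-gamma genes in 10-week COL ileum rose in 20 of 21 tested, 21 over the list (median 2.9, adjusted p = 1.1e-68, 7.9e-05 estimated). Genes of MHC class II rose in 8 of 11 tested (median 4.08, or 3.86 with members at their floor, adjusted p = 1.8e-21, 0.0066 estimated). H2-DMb1 (4.53 ± 0.27) rose. Genes of type I interferon rose in 10 of 22 tested, 11 over the list (median 1.16, adjusted p = 4.7e-08, 0.063 estimated). The virus tether Bst2 (3.20 ± 0.56) rose among them. T cell genes rose in 15 of 19 tested, 18 over the list (median 3.41, adjusted p = 8.6e-17, 0.033 estimated), with the T-cell receptor chain Cd3d up 71.8-fold (95% interval 19.5 to 598). B and plasma cell genes rose in 5 of 16 tested (median 3.43, adjusted p = 3.8e-11, 0.087 estimated). Follicle genes moved with them, at 2.46, 4.14 and 2.9 log2 in COL and 2.04, -1.77 and -1.23 in GF. Bacteria-induced genes rose in 11 and fell in 1 of 18 tested, 13 up and 1 down over the list (median 2.20, adjusted p = 1.3e-17, 0.026 estimated). The chemokine Ccl28 (1.53 ± 0.22) rose among them. Paneth cell, tuft and mast cell, immediate early and proliferation genes, with the mast cell protease Mcpt2 (4.17 ± 0.85) and Jun (1.08 ± 0.21), were called upward with medians 0.69, 1.56, 0.33 and 0.28 (adjusted p = 0.028, 0.017, 0.0039 and 0.027, and 0.53, 0.052, 0.052 and 0.46 estimated). Fat absorption genes fell in 5 of 19 tested, 6 over the list (median -0.30, adjusted p = 0.00016, 0.13 estimated). Fabp2 (-1.15 ± 0.23) and Apoa1 (-1.03 ± 0.21) fell among them. Guca2a (-1.13 ± 0.19) fell within the colonocyte list, and sterol and colonocyte genes were called downward with medians -0.40 and -0.35 (adjusted p = 1.5e-05 and 6.3e-06, and 0.1 and 0.033 estimated). Without replicate 1 of both germ-free groups, adjusted p was 0.14 for Paneth cell, 0.14 for proliferation and 0.052 for tuft and mast cell genes.

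**Figure D3:**
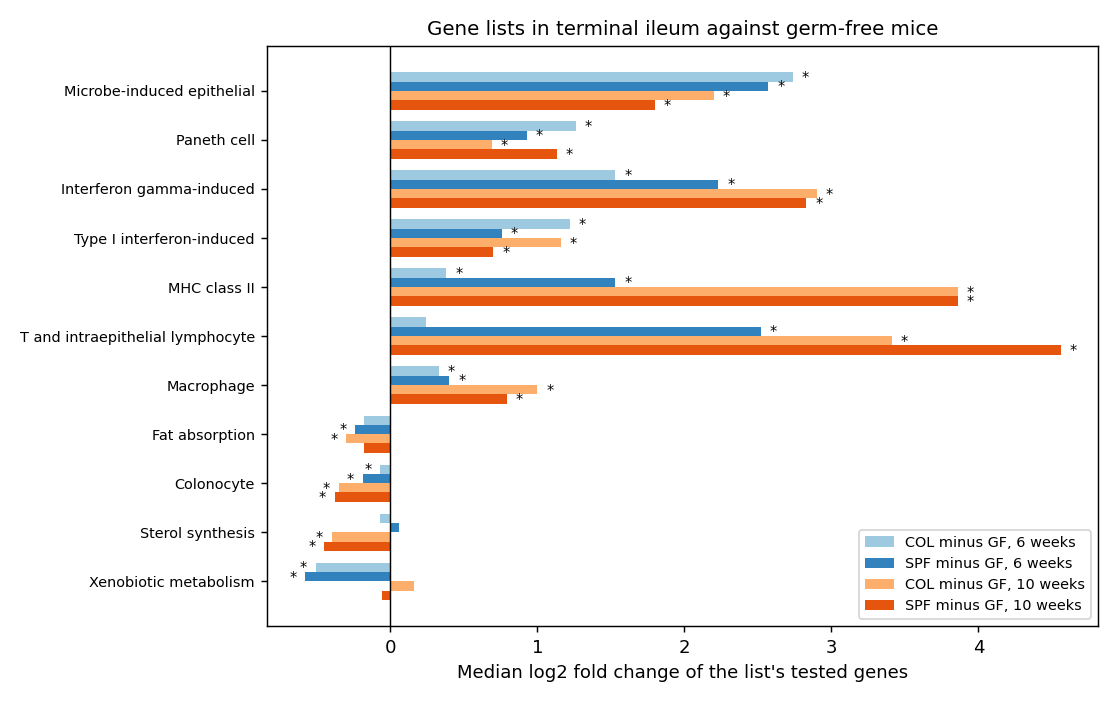
Median log2 fold change of 11 gene lists in ileum for SPF and COL minus GF at 6 and 10 weeks, with members that have a group at 3 counts or fewer set to that floor; bars start at 0, and a star marks a camera adjusted p under 0.05. MHC class II genes stood at 0.38 in 6-week COL and 3.86 in 10-week COL ileum.

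COL against SPF ileum at 10 weeks asks whether late and lifelong colonization differ in older tissue. Ahsa2 (chromosome 11, 23487882 to 23498030), an activator of the chaperone Hsp90, was higher in COL (63.2 ± 3.36 against 23.7 ± 1.36 CPM, log2 fold change 1.42 ± 0.19, adjusted p = 0.00068). In replicates 1, 2 and 3 the heat-shock gene Hspa1b was 428, 476 and 767 CPM in COL and 24.1, 28.7 and 39.4 CPM in SPF, and Hsp90aa1 (1.24 ± 0.19, adjusted p = 0.0072) was higher in COL (range over alternatives 4.7e-06 to 0.13). Efna2 (2.30 ± 0.39, adjusted p = 0.011) was higher, with adjusted p = 0.052 without COL replicate 1 (range 9.4e-05 to 0.24). In all 9 genes were higher and 3 lower in COL. The total of 12 became 5 and 5 without COL replicates 2 and 3 and 97 (36 higher, 61 lower) and 7 without SPF replicates 1 and 2. T cell genes lay lower in COL (median -1.09, 6 down of 19 over the list, adjusted p = 1.7e-06, 0.31 estimated), as did fat absorption, Paneth cell, bile acid and goblet genes with medians -0.20, -0.47, -0.42 and -0.22 (adjusted p = 0.00062, 0.00027, 0.012 and 0.015, and 0.31, 0.5, 0.31 and 0.5 estimated). Smooth muscle, matrix, immediate early, macrophage and bacteria-induced genes lay higher with medians 0.68, 0.49, 0.18, 0.16 and 0.18 (adjusted p = 3.4e-10, 6.9e-07, 0.0013, 0.016 and 0.017, and 0.31, 0.11, 0.13, 0.31 and 0.63 estimated). Without SPF replicate 3, whose smooth muscle genes had a median of 3.36 log2 CPM against 6.46 and 6.79 in the other two, the smooth muscle median was 0.24 (adjusted p = 0.00016), Paneth cell genes had adjusted p = 0.57, goblet 0.45 and bile acid genes 0.35, and interferon-gamma genes, at 0.085 with all libraries, 0.00016. Without SPF replicate 1, bacteria-induced genes had 0.86 in the other direction, and B and plasma cell, colonocyte and enteroendocrine genes, each at 0.085 with all libraries, had 0.00015 (higher in COL), 0.047 and 0.003 (lower). The macrophage genes Csf1r (0.18 ± 0.29, adjusted p = 0.93) and Cx3cr1 (0.03 ± 0.31, adjusted p = 0.99) did not pass.

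Age, 10 against 6 weeks, was compared within each status of the ileum to ask what changes between these ages with and without microbes. In GF ileum 4 genes fell, among them Acot1 (-1.81 ± 0.30, adjusted p = 0.017), Pdk4 (-1.65 ± 0.30, adjusted p = 0.031) and Acaa1b (-1.51 ± 0.25, adjusted p = 0.017), which act in fatty acid use. Without 10-week replicate 2 edgeR called 1 gene, which rose and is not among these, and 0 without any other of the 6 libraries, with 503 genes at unadjusted p under 0.05 and 10 by DESeq2 over all 6. Matrix genes lay lower at 10 weeks (median -0.55, 5 down of 15 over the list, adjusted p = 1.3e-06, 0.12 estimated), as did macrophage genes (median -0.23, adjusted p = 0.031, 0.47 estimated), and proliferation genes lay higher (median 0.22, adjusted p = 0.00063, 0.81 estimated). Without replicate 1 of both ages macrophage genes had adjusted p = 0.13, and type I interferon genes, at 0.69 with all libraries, had 0.029 in the other direction.

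In COL ileum, where age and time since colonization run together, Jchain rose from 6 to 10 weeks (1090 ± 198 against 46.3 ± 16 CPM, log2 fold change 4.57 ± 0.40, adjusted p = 1.8e-05). Ly6c2 (4.52 ± 0.31), Ceacam10 (5.23 ± 0.55), Cd74 (3.09 ± 0.34) and Apoe (1.45 ± 0.23), a lipoprotein gene of macrophages, rose, and Mptx2 (-3.90 ± 0.53) and Fabp1 (-3.88 ± 0.58) fell. In all 214 genes rose and 121 fell. The total of 335 became 67 and 158 without 10-week replicates 2 and 3 and 200 and 54 without 6-week replicates 2 and 3. Genes of MHC class II rose in 7 of 11 tested, 8 over the list (median 3.02, adjusted p = 1.7e-18, 0.02 estimated). Interferon-gamma genes rose in 11 of 21 tested, 18 over the list (median 1.39, adjusted p = 1.4e-22, 0.018 estimated). T cell genes rose in 7 of 19 tested, 18 over the list (median 3.19, or 2.88 with members at their floor, adjusted p = 1.4e-17, 0.038 estimated). B and plasma cell genes rose in 4 of 16 tested, 14 over the list (median 5.10, or 4.71 with members at their floor, adjusted p = 2.9e-18, 0.061 estimated). Follicle genes rose with them, from -1.78, -1.54 and -1.78 log2 to 2.46, 4.14 and 2.9. Monocyte and neutrophil genes rose in 1 of 6 tested (median 0.70, adjusted p = 0.00048, 0.03 estimated). Macrophage genes rose in 2 of 19 tested, 7 up and 1 down over the list (median 0.43, adjusted p = 7e-04, 0.061 estimated). Paneth cell genes fell in 4 of 15 tested, 9 over the list (median -0.97, adjusted p = 3e-11, 0.11 estimated). Bacteria-induced genes fell in 2 of 18 tested, 4 over the list (median -0.75, adjusted p = 0.03, 0.47 estimated). Sterol, fat absorption, type I interferon, goblet, enteroendocrine, stem and colonocyte genes lay lower, with medians -0.33, -0.23, -0.45, -0.22, -0.34, -0.28 and -0.34 (adjusted p = 7.3e-06, 8e-05, 0.016, 0.014, 0.014, 0.022 and 0.039, and 0.13, 0.15, 0.4, 0.33, 0.33, 0.19 and 0.3 estimated), and cytokine, xenobiotic and adipose genes higher, with medians 1.05, 0.57 and 2.77 (adjusted p = 0.013, 0.013 and 0.039, and 0.13, 0.26 and 0.53 estimated).

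In SPF ileum Apoa4 (chromosome 9, 46240696 to 46243459), a lipoprotein gene of enterocytes, rose from 6 to 10 weeks (1.55 ± 0.21, adjusted p = 0.0014), with adjusted p = 0.061 without 6-week replicate 2 (range 8.8e-09 to 0.061). In all 76 genes rose and 105 fell. The total of 181 became 71 and 416 without 10-week replicates 1 and 2, 5 without 6-week replicate 1, and 0 by edgeR without 6-week replicate 2, with 2475 genes at unadjusted p under 0.05 and 592 by DESeq2 over all 6. Sterol synthesis genes fell in 4 of 20 tested, 1 up and 9 down over the list (median -0.51, adjusted p = 6.9e-08, 0.27 estimated). Bacteria-induced genes fell in 1 of 18 tested, 1 up and 8 down over the list (median -0.89, adjusted p = 9.4e-06, 0.4 estimated). T cell genes rose in 2 of 19 tested, 11 over the list (median 1.63, adjusted p = 1.9e-07, 0.4 estimated). B and plasma cell genes lay higher (median 5.12, or 5.20 with members at their floor, 10 up of 16 over the list, adjusted p = 0.019, 0.77 estimated), as did MHC class II, interferon-gamma and adipose genes with medians 1.43, 0.38 and 2.23 (adjusted p = 0.00023, 0.0093 and 0.048, and 0.4, 0.63 and 0.77 estimated), and matrix and smooth muscle genes lay lower with medians -0.48 and -0.86 (adjusted p = 0.00014 and 9.5e-09, and 0.27 and 0.4 estimated). Follicle genes were at 5.27 log2 in 10-week replicate 1 and -0.93 and -1.39 in the other two. Without that library B and plasma cell genes had a median of 0.73 (adjusted p = 0.31) and adipose genes 0.13, while type I interferon, fat absorption and Paneth cell genes, at 0.58, 0.46 and 0.58 with all libraries, lay higher at 0.031, 0.013 and 0.03, Paneth cell genes in a changed direction. Without 10-week replicate 3, the library low in smooth muscle genes, these had a median of -0.40 (adjusted p = 1.5e-05), interferon-gamma genes adjusted p = 0.38 and Paneth cell genes 3e-04, and with the scaling of DESeq2 in place of TMM adipose genes had 0.052.

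Whether the difference of COL or SPF from GF ileum changed with age was tested as an interaction, the difference at 10 weeks minus that at 6 weeks. For COL, 17 genes had a more positive difference at 10 weeks and 2 a more negative one. Ceacam10 (6.60 ± 1.00, adjusted p = 0.0081), Jchain (4.50 ± 0.52, adjusted p = 0.001), Ly6c2 (3.32 ± 0.47), Cd74 (3.53 ± 0.48) and Selplg (3.90 ± 0.55), a selectin ligand of leukocytes, passed upward and the stress kinase gene Sgk1 (chromosome 10, 21882184 to 21999903) passed downward (-1.38 ± 0.22, adjusted p = 0.0028). MHC class II (median 3.48, or 3.42 with members at their floor, 7 up of 11 over the list, adjusted p = 1.7e-19, 0.024 estimated), interferon-gamma (median 1.48, 11 up of 21 over the list, adjusted p = 5.5e-16, 0.024 estimated), macrophage (median 1.09, 6 up and 1 down of 19 over the list, adjusted p = 9.2e-06, 0.024 estimated) and T cell genes (median 4.09, or 3.79 with members at their floor, 13 up of 19 over the list, adjusted p = 5.5e-16, 0.065 estimated) were called upward, and Paneth cell genes downward (median -0.96, 5 down of 15 over the list, adjusted p = 2.5e-09, 0.17 estimated). The total of 19 became 29 without 10-week COL replicate 1 and 31 without 6-week GF replicate 3. For SPF, 2 genes passed, Apoa4 (1.79 ± 0.30, adjusted p = 0.015) and Sgk1 (-1.34 ± 0.22, adjusted p = 0.015), with ranges over alternatives of 4.9e-05 to 0.36 and 1.8e-05 to 0.36. That count became 5 without 10-week SPF replicate 2, 13 without 6-week SPF replicate 3, and 0 by edgeR without 6-week SPF replicate 1 or 2, 10-week GF replicate 1 or 3, or 6-week GF replicate 1 or 2, while 1132 genes had unadjusted p under 0.05 and DESeq2 called 30 with all libraries. T cell (median 2.62, or 2.53 with members at their floor, 4 up of 19 over the list, adjusted p = 7.9e-08, 0.51 estimated) and MHC class II genes (median 2.07, 6 up of 11 over the list, adjusted p = 5.9e-06, 0.51 estimated) were called upward. Csf1r (1.09 ± 0.41, adjusted p = 0.34) did not pass for COL.

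Whether COL and SPF differed by tissue, untreated at 10 weeks, was tested as the colon difference minus the ileum difference. By edgeR 0 of 13807 genes passed, with 914 at unadjusted p under 0.05 and 5 by DESeq2. The count became 1 without colon COL replicate 3, 1 and 8 without colon SPF replicates 1 and 3, and 7 without ileum SPF replicate 1. Matrix genes were called downward (median -0.80, 4 down of 17 over the list, adjusted p = 3.3e-07, 0.0097 estimated), among them the collagen gene Col1a1 (-1.06 ± 0.32, adjusted p = 0.63), as were smooth muscle genes (median -0.77, adjusted p = 2.7e-07, 0.81 estimated), and fat absorption genes upward (median 0.38, 6 up of 19 over the list, adjusted p = 0.00013, 0.17 estimated). Without ileum SPF replicate 3, low in smooth muscle genes, the smooth muscle median was -0.37 and its call was lost (adjusted p = 0.065), while bacteria-induced and proliferation genes, at 0.11 and 0.16 with all libraries, had 0.0031 and 0.029. Without ileum SPF replicate 1, Paneth cell, type I interferon, interferon-gamma and B and plasma cell genes, at 0.1, 0.14, 0.27 and 0.94 with all libraries, had 0.001, 0.0089, 0.042 and 0.0069. Pancreas and liver genes, testable in this comparison alone, had adjusted p = 0.94.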

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

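The tests of where germ-free ileum lies, of nerve and glia genes, of follicles for 3 genes and of age alone, and list results without single libraries, were chosen only after the result was seen. The differences below were each called by an interaction test of whether an effect differs between groups. For DSS in COL against SPF colon, where edgeR called 0 genes (1122 at unadjusted p under 0.05, 17 by DESeq2), and across tissues, where edgeR called 0 (914 at unadjusted p under 0.05, 5 by DESeq2), all 100 and all 60 splits gave as many because none can give fewer than 0, so they say nothing about chance; the highest others gave 15 and 173, and the last points to a structure of the samples. Other splits do not exclude chance for the other two counts. For SPF by age, 12 of 100 splits gave at least the real 2 genes and the highest other gave 358. For COL by age, 10 of 100 gave at least the real 19 and the highest other 378. The 11 and 9 other splits with as many were all among the 17 that left the groups of one age whole. Splits that mixed both ages gave at most 0 and 1 by edgeR. These counts therefore point to a structure of the samples, the large difference from GF at either age.

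In colon, the DSS effect in COL minus that in SPF differed in 7 lists, with medians goblet (0.82), xenobiotic (0.60), smooth muscle (0.46), matrix (0.30), immediate early (-0.28), interferon-gamma (-0.44), fat absorption (-0.21). Their calls were lost at adjusted p = 0.34 to 0.82 with an estimated correlation. Colon minus ileum, the COL against SPF difference had medians of matrix (-0.80), smooth muscle (-0.77), fat absorption (0.38); matrix genes had adjusted p = 0.0097 with an estimated correlation, smooth muscle genes 0.81 (and 0.065 with the preset one without 10-week SPF ileum library 3) and fat absorption genes 0.17.

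In ileum, the SPF minus GF difference at 10 minus that at 6 weeks was 1.79 for Apoa4 and -1.34 for Sgk1, with list medians B and plasma cell (5.36, or 5.4 with members at their floor), adipose (3.51), T cell (2.62, or 2.53 with members at their floor), MHC class II (2.07), xenobiotic (0.44), interferon-gamma (0.38), bacteria-induced (-0.86), smooth muscle (-0.67), sterol (-0.41). All 9 lists lost their call, at adjusted p = 0.51 to 0.74 with an estimated correlation. Follicle genes were high in the 10-week SPF library numbered 1 (5.27 log2 above the ileum mean, the other two -0.93 and -1.39). Without it adjusted p was 0.39 for B and plasma cell (median 1.00), 0.068 for bacteria-induced and 0.15 for xenobiotic genes, and type I interferon (0.025), fat absorption (0.0011) and immediate early genes (0.032) gained a call. Without number 3, adjusted p was 0.24 for interferon-gamma, 0.069 for xenobiotic, 0.069 for smooth muscle and 0.00037 for Paneth cell genes. Without both GF libraries numbered 1 it was 0.26 for interferon-gamma, 0.94 for B and plasma cell and 0.13 for xenobiotic genes.

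The same difference for COL minus GF was called for Ceacam10 (6.60), Jchain (4.50), Selplg (3.90), Cd74 (3.53), Ly6c2 (3.32), Derl3 (3.11), Jdp2 (3.03), Itga4 (2.72), Cytip (2.48), H2-DMb1 (2.45), Gbp7 (1.89), Irgm2 (1.5), Psmb9 (1.48), Hook2 (-1.18) and Sgk1 (-1.38) among the named genes, with list medians B and plasma cell (6.08, or 5.87 with members at their floor), T cell (4.09, or 3.79 with members at their floor), adipose (3.64), MHC class II (3.48, or 3.42 with members at their floor), interferon-gamma (1.48), macrophage (1.09), monocyte and neutrophil (1.08), xenobiotic (0.62), matrix (0.46), Paneth cell (-0.96), bacteria-induced (-0.74, or -0.77 with members at their floor), colonocyte (-0.41), stem (-0.34), proliferation (-0.33), goblet (-0.27), fat absorption (-0.27), sterol (-0.18). Macrophage, MHC class II and interferon-gamma genes kept their call at adjusted p = 0.024 with an estimated correlation, and the other 14 lists lost theirs at adjusted p = 0.065 to 0.42 with an estimated correlation. Without both GF libraries numbered 1, adjusted p was 0.14 for stem, 0.00014 for type I interferon, 0.00093 for enteroendocrine and 0.05 for cytokine genes.

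Pattern 1 is that Efna2 and Sbsn, of 13807 genes, had SPF and COL libraries fully apart in the same direction in all 4 strata of tissue, age and treatment. With all 30 libraries scaled together, Efna2 (chromosome 10) was 0.555 to 6.64 CPM in SPF and 7.2 to 25 CPM in COL, and 8.37 to 17 CPM in GF ileum. Sbsn (chromosome 7) was 1.3 to 5.2 CPM in SPF and 0.396 to 3.3 CPM in COL, near the floor. Chance is argued against for the count of 2, untested per gene: 1 of 100 relabellings within the strata gave 2 genes, none more. One DNA stretch differing between colonies is argued against for both genes, on different chromosomes (0 within 5 Mb, as in most random sets). A stretch or variant at either stays open. A state of the COL mice alone is argued against for Efna2, since GF ileum lay with COL (mean position -0.15 over both ages, with COL at 0 and SPF at 1) and above every SPF library. For Sbsn (1.02, and 0.6 at 10 weeks) it cannot be told apart, being so near the floor. COL and GF mice may share a colony and early life without microbes, and both stay open and untested.

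Pattern 2 is that smooth muscle genes in the 10-week SPF ileum library numbered 3 had a median of 3.36 log2 CPM against 6.46 and 6.79 in the other two, a gap of 3.27. With the others thinned to that library's 2233837 counts the gap did not shrink (-0.59% lost), which tests only counting error. Low depth otherwise stays open. Less of the muscle wall in that sample may be the cause, since enteric nerve and glia genes lay there 1.59 log2 below the lower of the other two (value -1.59), at 0.45 against 2.04 and 2.43. Adipose genes were also low, at 0.45 against 5.16 and 4.79. Whether that comes from dissection or from a difference between mice was not tested.

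Pattern 3 is the 17 genes with a larger COL minus GF difference at 10 than at 6 weeks. Follicle genes moved with this comparison (2.46 to 4.14 log2 in 10-week and -1.78 to -1.54 in 6-week COL libraries). With the mean of 6 follicle genes as a covariate the median change of these 17 was 2.42 in place of 3.03. The share kept was 0.8, and 13 stayed called. Cmah, Cytip and Itga4 kept a median share of 0.63 and lost their call (adjusted p = 0.43, 0.13 and 0.46). Lymphoid follicles stay open: their level separates the COL ages fully, so the covariate's slope rests on spread within groups. With all ileum libraries thinned to 2233837 counts the median change was 3.25 (share 1.07), and 10 stayed called with fewer counts to test. This tests unequal counts only. Age alone (GF change is subtracted) is argued against as the whole source. Each 6-week COL library lay below 6-week SPF over genes raised without it, by medians of -2.12, -1.85 and -1.85 (upper quartiles -0.89, -0.7 and -1.16). Of these 15, 14 and 13 genes 13, 14 and 13 were among the 17. Time since colonization may account for this pattern, alone or with age, and stays open and untested.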

How the results depend on the processing

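The list results without single libraries, the results without both GF libraries numbered 1, and the block with only 6 libraries were chosen only after the result was seen. Counts are of called genes, and a change of over 1.5 times is given.

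With DESeq2 there were 1463 genes for DSS in COL colon, 28 for COL against SPF colon, 5 for COL against SPF colon after DSS, 17 for the difference of the DSS effects, 62 and 47 for COL against SPF ileum at 6 and 10 weeks, 10, 725 and 592 for age in GF, COL and SPF ileum, 30 and 154 for SPF and COL by age, and 5 across tissues. With no filter there were 8 for COL against SPF colon, 7 for SPF by age and 50 for COL by age. For these 2 settings the cause was not tested. The scaling of DESeq2 within edgeR changed no count by that much.

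With only the 6 libraries of 2 groups there were 1728 genes for DSS in SPF and 1839 in COL colon, 0 by edgeR for COL against SPF colon after DSS (1030 at unadjusted p under 0.05 with all libraries, 5 by DESeq2), 1604 for SPF against GF at 6 weeks, 66 and 4 for COL against SPF ileum at 6 and 10 weeks, 502 for SPF against GF at 10 weeks, and 636 and 29 for age in COL and SPF ileum; the cause was not tested.

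With replicate numbers as a block there were 0 genes by edgeR for COL against SPF colon after DSS, 6 for COL against SPF ileum at 10 weeks, 109 for age in SPF ileum and 29 for COL by age; the cause was not tested. In the comparison where the numbers pair, SPF against GF at 10 weeks, the block gave 750 genes in place of 821, no list changed its call, and with only its 6 libraries the block gave 753. A block within status left the count across tissues at 0 by edgeR (914 at unadjusted p under 0.05 without the block, 5 by DESeq2).

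Without both GF libraries numbered 1, which leaves fewer libraries, there were 672 and 389 genes for SPF and COL against GF at 6 weeks, and 0 by edgeR for age in GF ileum and for SPF by age (503 and 1132 at unadjusted p under 0.05 with all libraries, 10 and 30 by DESeq2). Type I interferon genes by age in GF ileum then changed direction with adjusted p = 0.029, against 0.69 with all libraries; the cause was not tested.

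Leaving out 1 library at a time gave 1915 to 3409 genes for DSS in SPF and 376 to 602 in COL colon, 0 to 94 for COL against SPF colon, 0 to 29 after DSS, 0 to 1 for the difference of the DSS effects, 513 to 944 and 311 to 751 for SPF and COL against GF and 8 to 18 for COL against SPF at 6 weeks, 437 to 1010, 713 to 1225 and 5 to 97 for the same at 10 weeks, 0 to 1, 54 to 320 and 0 to 416 for age in GF, COL and SPF ileum, 0 to 13 and 15 to 31 for SPF and COL by age, and 0 to 8 across tissues. The counts of 0 are by edgeR, with fewer libraries to test.

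Of 443 list results 190 were called. With a correlation estimated from the data 38 were, the other 152 keeping their direction, and with the scaling of DESeq2 189 were. The block changed 9 list calls (6 gained, 3 lost), leaving out the 10-week SPF ileum library numbered 3 changed 16 of 131 (7 gained, 9 lost), leaving out number 1 of that group changed 21 of 131 (15 gained, 6 lost), and leaving out the DSS-treated SPF colon library numbered 3 changed 9 of 78 (4 gained, 5 lost). Without both GF libraries numbered 1, 7 were gained and 11 lost. Without the 10-week SPF ileum library numbered 1 the direction changed, cause untested, for bacteria-induced genes in COL against SPF (adjusted p = 0.86, against 0.017 with all libraries and 4.2e-06 without number 3) and Paneth cell genes by age in SPF (0.03, against 0.58 and 3e-04).

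For named genes, no direction changed with its call in any alternative. Leaving out 1 library kept 2657 calls, ended 607 and added 60. DESeq2 kept 527 and added 96, no filter kept 510, ended 17 and added 22, the 6 libraries alone kept 436, ended 66 and added 51, the block kept 499, ended 28 and added 11, and the scaling of DESeq2 kept 525 and ended 2. Counts shared by 2 comparisons, not rerun without single libraries, kept within 1.5 times where rerun. Depth, 2233837 counts in the shallowest ileum library, limits what can be seen in genes near the floor of 3 counts, and folds against groups with no reads are lower bounds.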

Other observations

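The splits below were planned. Of the 6 libraries of 2 groups there are 10 splits, too few for a share under 0.05. The real count and the highest other split were 3097 and 0 for DSS in SPF colon, 918 and 0 for DSS in COL colon, 1018 and 0 for SPF and 614 and 0 for COL against GF ileum at 6 weeks, 13 and 4 for COL against SPF there, 821 and 1, 1209 and 0, and 12 and 16 for the same at 10 weeks, and 4 and 12, 335 and 0, and 181 and 10 for age in GF, COL and SPF ileum. For COL against SPF colon they were 0 and 0 by edgeR (988 genes at unadjusted p under 0.05, 28 by DESeq2), and after DSS 1 and 62, the last pointing to a structure of the samples other than status. Splits with as many genes as the real one, itself included, numbered 10 for untreated COL against SPF colon (any split has at least 0), 2 each for COL against SPF colon after DSS, COL against SPF ileum at 10 weeks and age in GF ileum, and 1 each for the rest.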
